A study of Mus musculus with 3 samples.

How the data were processed

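Immune cells of the mouse infrarenal aorta were measured by single-cell RNA sequencing in 3 libraries, Sham, AAA_7 and AAA_14, with 1 library per group. Per the labels' protocols, the tissue was digested with collagenase, hyaluronidase and DNase, CD45-positive cells were enriched with CD45 and viability microbeads, all aortas of a group were mixed (20 aneurysm and 50 control aortas, with no number given for AAA_7 by itself), and libraries were made with droplet-based 3' chemistry and a v2 reagent kit. Groups were taken from the sample titles. The title and the treatment label of AAA_7 disagree, because the label gives PBS. That sample is therefore called the library titled AAA_7, and AAA_14 against Sham, where title and treatment label go together, was taken as the main comparison.

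The authors deposited unnormalised UMI counts (unique molecular identifiers, the molecules counted) per gene and barcode, made with Cell Ranger 6.1.2 per the file headers. The submitters' processing notes name Cell Ranger, Seurat and the mouse build mm10, with no role or order. Reference annotation, read filters and any removal of doublets upstream are not given in the sources used here. Each file held 32285 genes and barcodes with at least 500 UMIs. No cell type annotation by the authors was used here. Gene positions came from the GENCODE vM21 annotation of GRCm38 (mm10), which shares 99.85% of the gene identifiers in the files and holds all 193 named genes.

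Of 17389 barcodes, those with at least 200 detected genes and at most 10% of UMIs from mitochondrial genes were kept. The limit removed 2534 barcodes (66.9%) of Sham, 263 (7.52%) of AAA_7 and 4766 (47.2%) of AAA_14. Doublets were called per library with Scrublet in scanpy 1.11.5. Its automatic threshold called 2, 0 and 0 cells in Sham, AAA_7 and AAA_14, under 0.5% of over 5000 cells. This was taken as a failed call, so the highest-scoring cells were removed at the expected rate of 0.8% per 1000 cells, which took 12, 83 and 224 cells. That rate was computed from the cells that passed the filters and not from all barcodes, so doublets may remain. Kept were 1223, 3146 and 5062 cells, 9431 in all.

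Genes found in at least 3 cells were scaled to 10000 counts per cell and log-transformed. From 2000 variable genes, without mitochondrial, ribosomal, haemoglobin, sex-linked and antigen receptor variable genes, 30 principal components were computed, and a graph of 15 nearest neighbours weighted by Jaccard overlap was partitioned with leidenalg 0.10.2 and igraph 0.11.9 at a resolution of 1 and a seed of 1. The 27 clusters were named from fixed marker lists, where at least 3 markers were detected in 10% of the cells and the 10 leading genes did not go against the name. A cluster stayed unnamed where the score of a second class reached 0.8 of the first. This ratio was set after the clusters were seen, and the shares it kept out are given with the results. Macrophage and monocyte clusters were joined as phagocytes, T and gamma-delta T cells as T cells, and conventional, mature and plasmacytoid dendritic cells as dendritic cells. No cluster of the 6 classes had more leading markers of another class than of its own. Classes with at least 50 cells in both libraries were compared, which gave 14 of 18 pairs of class and libraries. Phagocytes and dendritic cells of Sham, 13 and 40 cells, were too few.

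Counts were summed per class and library and divided by the class total and given as CPM, the usual scale for sequencing counts. Ratios are log2 ratios of CPM with 0.5 counts added to each sum, with a 95% interval from the exact conditional binomial distribution. Shares carry exact Clopper-Pearson 95% intervals. The intervals of ratios and shares cover counting error only, not variation between libraries, and those of ratios leave out variation between cells. A fold against 0 counts was computed against a floor of 3 counts in that library. For 35 gene lists, the median log2 ratio was taken over members with at least 10 UMIs in both libraries together, with an order-statistic interval over members and, as a description only, the percentile among 10000 random lists matched on expression in 20 bins. This gave 91 medians. The 24 that are treated as answering a comparison were picked after the medians were seen. List names in the text are those of the fixed lists, which were for phagocytes tissue-resident macrophage, inflammatory cytokines and inflammasome, chemokines, matrix-degrading proteases, protease inhibitors, lipid-associated macrophage, wound repair and alternative activation, interferon-stimulated, MHC class II, MHC class I, complement, glycolysis, hypoxia, oxidative phosphorylation, iron and heme handling and early monocyte, with further lists for the other classes and dissociation and cell cycle lists for all.

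Ranked genes had at least 30 UMIs and 50 CPM in the higher library and, to limit RNA released from other cells, at least 0.1 of the CPM of the highest other class. Mitochondrial, ribosomal, haemoglobin, Xist and Y-linked genes, Gm and Rik gene models, antigen receptor segments and markers of other classes were left out of the ranking. They were ranked by the interval bound nearest to no change, and the first 10 each way for phagocytes and 3 for other classes were taken. The 2 most abundant and the 2 most changed members of each list were added. These needed at least 30 UMIs in the higher library but passed none of the other filters of the ranking. This gave 397 ratios. In 36 of them at least 20% of the gene's UMIs in the higher library came from 1 cell, which is said beside the genes named. The lower library was not screened in this way. Ligand and receptor levels were computed for 37 fixed pairs. The pair of Ccl19 was left out because its symbol names more than 1 gene in the files. Some items that the rule or the cluster lists give are not reported here.

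Filters, classes, markers, lists, pairs, the rule for named genes and the first set of alternatives were chosen before the data were examined. The alternatives were mitochondrial limits of 5% and 20%, at least 500 genes per cell, doublets kept, Leiden resolutions of 0.5 and 2, separate clustering, naming of single cells, thinning to 1000 UMIs, 5 counts added, other UMI minimums for list members (1 and 100), centring on the median gene, TMM factors from edgeR 4.0.16 in R 4.3.3, and the mean over cells of log2 levels. Chosen after seeing the data were the 20% limit for genes and lists, the removal of the limit for shares, a limit per library at the median plus 3 median absolute deviations (19.3%, 4.04% and 21.3% in Sham, AAA_7 and AAA_14), CPM without mitochondrial genes, and ratios without the cell that held most UMIs of the gene in each library.

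The ratio and list steps were tested on simulated Poisson counts with known answers. The interval assumes this model, so the test checks the computation and not variation between cells or libraries. Changed genes were drawn from those with at least 10 counts expected in each library. For phagocytes (12323 genes, AAA_14 against AAA_7), neutrophils (8883), T cells (11604) and B cells (11366, each AAA_14 against Sham), the interval of unchanged genes held 0 in 96.0%, 97.1%, 95.3% and 96.6% of genes, and it excluded 0 for 94%, 84%, 92% and 85% of genes changed 2-fold and for 100%, 100%, 100% and 99% of genes changed 4-fold. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9.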

Results

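Immune cells of the infrarenal aorta, the abdominal segment below the renal arteries, were profiled cell by cell in wild-type mice in 3 libraries, Sham, AAA_7 and AAA_14, where AAA is abdominal aortic aneurysm. The series set out to describe the immune cells of aneurysmal and normal mouse aortas and how their subgroups and genes differ. By their treatment labels, Sham aortas received phosphate-buffered saline (PBS) and AAA_14 aortas elastase, an enzyme that degrades the elastic fibres of the vessel wall. The title of AAA_7 names an aneurysm while its treatment label names PBS, so it is called the library titled AAA_7 here, and values from it are those of a library whose treatment is in doubt. The unit of 7 and 14 is not given in the labels. Each group was 1 library made from pooled aortas, so there were no replicates and no test between groups, and every difference is one between libraries. Intervals of shares and of single genes cover counting error only. Those of list medians cover the spread over members, which are treated as independent.

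The Sham library held 13677839 UMIs in 3785 barcodes, AAA_7 13341534 in 3496 and AAA_14 67243700 in 10108. After filtering, 1223, 3146 and 5062 cells remained, with a median of 3640, 2533 and 6740.5 UMIs per cell. At these cell numbers a count of 0 allows a share of up to 0.245%, 0.0954% and 0.0593%. This limit is 3 counts of the total and lies below the exact upper bound used for the other shares (0.301% for 0 of 1223 cells). As a check of the CD45 bead selection, cells with at least 3 fibroblast markers made up 0.409%, 0.540% and 2.61%, and those with at least 3 smooth muscle markers 0% (which allows 0.245%), 0.223% and 0.849%. Endothelial markers were found in this way in 0.0818%, 0.286% and 0.612% of cells and erythroid markers in 1.06%, 0.0636% and 2.35%. The mitochondrial share differed between the libraries within each class: in T cells it was 8.05% of UMIs in Sham, 1.84% in AAA_7 and 7.07% in AAA_14, and in neutrophils 2.08%, 0.767% and 4.68%.

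Phagocytes, the macrophages and monocytes that engulf debris and remodel tissue, were nearly absent from the Sham library and abundant in the other libraries. They made up 13 of 1223 Sham cells (1.06%, interval 0.567 to 1.81%), 31.6% (29.97 to 33.25%) of AAA_7 cells and 21.9% (20.8 to 23.1%) of AAA_14 cells. Lymphocytes dominated Sham, where T cells were 35.9% (33.2 to 38.7%) and B cells 33.9% (31.3 to 36.7%), against 17.9% (16.6 to 19.3%) and 14.5% (13.3 to 15.7%) of AAA_7 and 18.2% (17.2 to 19.3%) and 24.9% (23.7 to 26.1%) of AAA_14. Neutrophils, the first granulocytes to enter injured tissue, were 8.42% (6.93 to 10.1%) of Sham, 21.8% (20.3 to 23.3%) of AAA_7 and 15.2% (14.2 to 16.2%) of AAA_14. Dendritic cells, which present antigen to T cells, were 3.27% (2.35 to 4.43%), 6.68% (5.83 to 7.60%) and 8.61% (7.85 to 9.42%), and natural killer (NK) cells 7.03% (5.66 to 8.61%), 5.28% (4.52 to 6.12%) and 2.07% (1.70 to 2.51%).

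**Figure D1:**
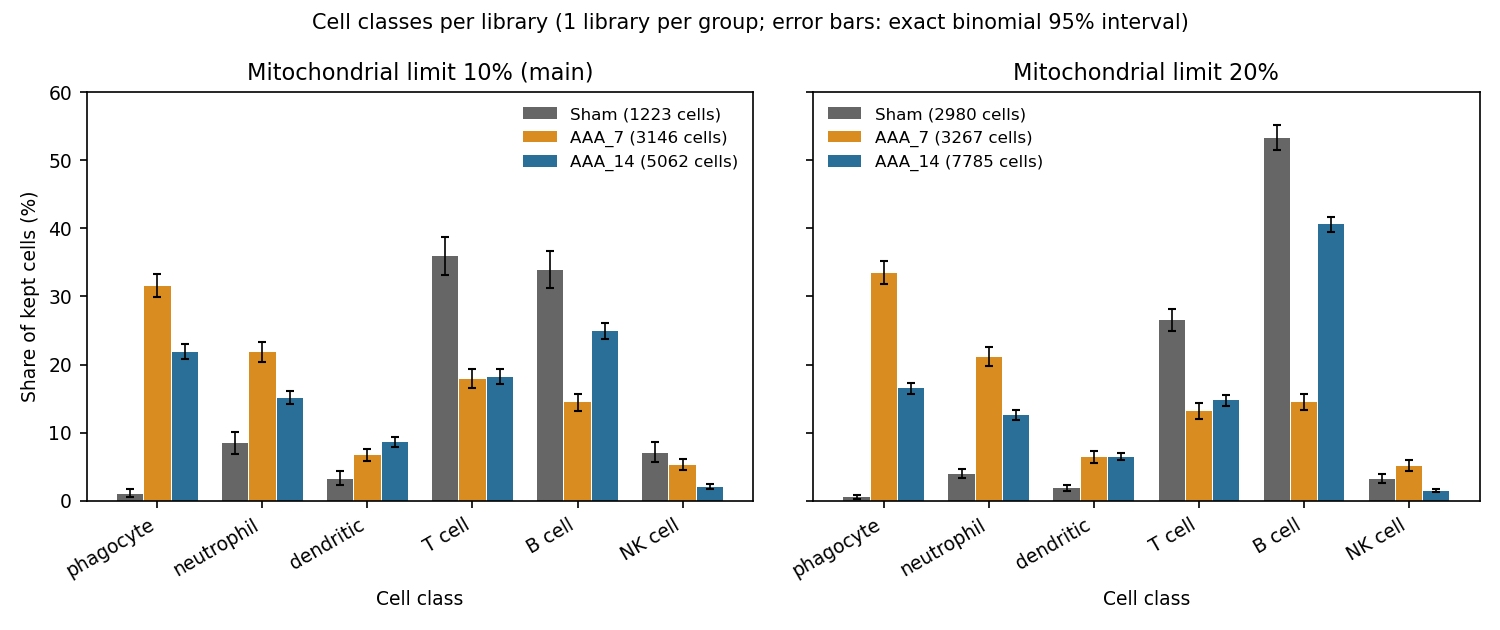
Bars give the share of kept cells (percent, vertical axis) in each cell class (horizontal axis) for the 3 libraries with mitochondrial limits of 10% (left) and 20% (right), and error bars the exact binomial 95% interval. Phagocytes were 1.06% of Sham, 31.6% of AAA_7 and 21.9% of AAA_14 cells at 10% and 0.537%, 33.5% and 16.5% at 20%.

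These are shares of cells that passed a CD45 bead selection, whose effect on them was not analysed here, and a mitochondrial limit, which removed 66.9% of Sham barcodes and 7.52% of AAA_7 barcodes. With a limit of 5% only 133 Sham cells remained and Sham neutrophils were 72.2%, above both other libraries. Phagocytes were then 32.7% of AAA_14 and 27.9% of AAA_7, the opposite order to that at 10%. The order of AAA_14 and AAA_7 also turned for neutrophils and B cells. In AAA_14 these were 25.6% and 4.56% at 5%. In AAA_7 they stayed within their intervals at 10%, which were 20.3 to 23.3% and 13.3 to 15.7%. T cells and B cells of Sham were 1.50% each at 5%, on 2 cells each. With a limit of 20% Sham was 53.3% B cells and 3.96% neutrophils. NK cells were then 3.22% of Sham and 5.17% of AAA_7, and 3.11% and 5.27% with no limit, the opposite order to that at 10%. Dendritic cells were 6.37% of AAA_7 and 6.49% of AAA_14 at 20%, and 5.74% and 4.92% with no limit. The phagocyte share of Sham lay between 0% and 1.94% in every setting run. Different clusters made up the classes. Neutrophil cluster 3, led by Csf1, Acod1, Slc7a11 and Il1a, held 655 of 685 AAA_7 neutrophils, while clusters 8 (Csf3r, Cxcr2) and 10 (Mmp8, Ly6g, Ltf) held 43 and 58 of 103 in Sham and 401 and 245 of 767 in AAA_14. Phagocyte cluster 6, led by Adora2b, Spp1, Thbs1 and Vegfa, held 537 of 994 AAA_7 and 80 of 1108 AAA_14 phagocytes, cluster 2 (Fcrls, Ccl8, Mrc1) 289 and 506, cluster 7 (Ly6i, Cx3cr1) 130 and 431 and cluster 17 (Retnla, Ccl24, Lyve1) 38 and 91. Naive T cell cluster 1 (Dapl1, Lef1) held 313 of 439 Sham, 214 of 563 AAA_7 and 436 of 922 AAA_14 T cells, and cluster 5 (Ctla4, Icos, Ikzf2) 102, 277 and 353. B cell cluster 4 held 316 of 415 Sham B cells, 164 of 455 in AAA_7 and 280 of 1259 in AAA_14, and cluster 0 (Ighd, Cr2) 94, 282 and 741. Of dendritic cells, cluster 11 (Cd209a) held 116 of 210 in AAA_7 and 173 of 436 in AAA_14, and cluster 14 (Xcr1, Clec9a) 33 and 116. Unnamed clusters were 8.18% of Sham, 0.922% of AAA_7 and 2.88% of AAA_14, of which cluster 18, with T and B cell markers together, was 6.87%, 0.159% and 0.356%. Outside the compared classes, type 2 innate lymphoid cells were 1.55%, 0.413% and 1.30%, erythroid cells 0.245%, 0% (which allows 0.0954%) and 0.849%, endothelial cells 0% (which allows 0.245%), 0.223% and 0.454%, and cluster 22 with the granule precursor genes Elane, Ms4a3 and Prtn3 1.06%, 0.445% and 1.22%.

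Within classes the median gene itself lay above 0 against Sham, by a log2 ratio of 0.19 in AAA_14 and 0.45 in AAA_7 neutrophils, 0.44 and 0.41 in T cells, 0.32 and 0.17 in B cells and 0.11 and 0.18 in NK cells, and by 0.12 between AAA_14 and AAA_7 in dendritic cells. Medians relative to it are called centred below. Of 91 list medians, 54 had an interval over members that includes 0, and 33 of these lay on the other side of 0 in at least 1 alternative, so no direction is read from a median whose interval includes 0. Of the 37 others 7 did, and each of these is given with its alternative. One alternative, the mean over cells of log2 levels, is another scale. Positions are on GRCm38.

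Interferon-stimulated genes, antiviral effectors switched on by type I interferon, were far higher in AAA_14 than in Sham neutrophils, and so were the same 10 genes in AAA_7. In AAA_14, 9 of 10 measured members were at least 2-fold higher, with a median log2 ratio of 3.14 (interval over members 1.92 to 5.19, centred 2.96). Ifit1, an RNA-binding antiviral protein, had 1477 UMIs in AAA_14 against 4 in Sham, a log2 ratio of 5.19 (4.0002 to 7.2373). Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731) had 920 against 1, a ratio of 6.09 (4.19 to 11.98), and Slfn5, another interferon-induced gene (chromosome 11, 82951349 to 82964840), 1116 against 1, a ratio of 6.37 (4.47 to 12.26). Ifitm1, which blocks viral entry, was abundant in both and 2.38 (2.20 to 2.57) higher. In AAA_7 9 of 10 members were higher as well, with a median of 3.28 (2.23 to 5.38, centred 2.83), and between AAA_14 and AAA_7 the median was 0.01 (−0.27 to 0.54, and −0.69 with a limit of 5%), with Isg15 the 1 member at least 2-fold lower in AAA_14 (−1.85). The same 10 genes were also higher in other classes of AAA_14 than of Sham, with medians of 2.15 in T cells, 2.18 in B cells and 1.08 in NK cells (9 measured), and of AAA_7, with medians of 2.15 in T cells, 2.32 in B cells (8 measured) and 1.45 in NK cells (9 measured). The neutrophil median over Sham was 1.96 with a mitochondrial limit of 5% and 0.95 as a mean over cells, and in AAA_7 2.57 with cells thinned to 1000 UMIs and 0.61 as a mean over cells.

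Activation genes of neutrophils, which encode cytokines and chemokines, were higher in both libraries than in Sham and highest in AAA_7, where granule protein genes were low. In AAA_14, 9 of 14 activation genes were at least 2-fold higher than in Sham, with a median log2 ratio of 1.30 (0.71 to 2.04, centred 1.11), and in AAA_7 13 of 14, with a median of 2.73 (2.09 to 4.60, centred 2.28). Tnf, the gene of tumour necrosis factor (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), stood at 36.5 CPM in Sham, 4072 in AAA_7 and 362 in AAA_14, ratios over Sham of 6.76 (6.1005 to 7.6093) and 3.27 (2.61 to 4.12). Ccl3, a chemokine for monocytes, was 5.05 (4.80 to 5.34) and 2.23 (1.97 to 2.51) higher, Cxcl2, a neutrophil attractant, 2.52 and 0.95, and Il1b 2.20 and 1.03. Saa3, an acute-phase gene (chromosome 7, 46711998 to 46715700), had 1094 UMIs in AAA_7 and 0 in Sham, at least 120.0-fold higher, and Cxcl1 had 651 against 1 (ratio 7.16, 5.26 to 13.05). Saa3 is also among the leading genes of phagocyte cluster 6, and RNA released from those cells was not tested as its source. Between AAA_14 and AAA_7 the activation median was −1.76 (−2.83 to −0.86), with 11 of 14 members at least 2-fold lower in AAA_14, among them Tnf (−3.49, −3.58 to −3.41), Ccl4 (−2.95) and Cxcl2 (−1.57), and with Saa3 (−5.02) and Lsmem1 (−4.39) leading the ranking. With a limit of 5% the activation median of AAA_14 over Sham was 0.35, with Cxcl2 at 0.13 and Il1b at 0.20, and that of AAA_14 over AAA_7 −2.64.

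Granule protein genes, which neutrophils express while they mature in the bone marrow, were at least 2-fold lower in AAA_7 than in Sham for 8 of 10 members, with a median of −2.27 (−2.87 to −0.70, centred −2.72). Camp, the gene of the antimicrobial peptide cathelicidin (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617), stood at 18767 CPM in Sham and 1449 in AAA_7 (−3.70, −3.77 to −3.62), and Ly6g, the neutrophil surface marker, was −4.09 (−4.54 to −3.69). In AAA_14 no granule gene differed 2-fold from Sham (median −0.28, −0.83 to 0.16), and against AAA_7 7 of 11 were at least 2-fold higher (median 1.97, −0.27 to 2.71), led by Camp (2.78), Ltf (2.71) and Ngp (2.58), with Olfm4 at 3.43 (2.67 to 4.45). Ltf and Ly6g lead cluster 10, which held 99.99%, 98.8% and 99.8% of the neutrophil UMIs of Camp in Sham, AAA_7 and AAA_14 and 100%, 95.6% and 99.8% of those of Ltf, so the ratios of Camp and Ltf and that cluster are 1 observation. Of the Ly6g UMIs it held 96.5%, 61.8% and 87.6%, with 38.2% of those of AAA_7 in cluster 3. Genes of mature circulating neutrophils had medians of 0.28 (−0.70 to 0.81), −0.19 (−2.59 to 1.26) and 0.53 (−0.98 to 1.89) for AAA_14 over Sham, AAA_7 over Sham and AAA_14 over AAA_7, with Retnlg at −2.59 in AAA_7. Lower in AAA_14 than in Sham were Thbs1 (−2.02), Ppp1r10 (−1.86) and Impact (−1.65). Cell cycle genes had medians of 0.60 (0.00 with members at 0 counts placed at their bound), 0.49 and 0.37. None kept its direction. The first was −0.97 with 5 counts added, the second −0.58 with at least 500 genes and −0.78 with a limit of 20%, and the third −0.63 with doublets kept and −0.59 with cells thinned. The dissociation and stress list, which marks enzymatic digestion, had medians of 0.35 (0.03 to 0.60), 0.29 and −0.02, of which the first was −0.23 with a limit of 5%.

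Type 17 genes, which mark T cells that make interleukin 17, were higher in both libraries than in Sham for all 9 measured members. The median log2 ratio was 3.03 (2.76 to 5.17, centred 2.58) in AAA_14 and 2.87 (2.10 to 4.14, centred 2.45) in AAA_7. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) had 648 UMIs in AAA_14, 87 in AAA_7 and 6 in Sham, ratios over Sham of 5.18 (4.16 to 6.74) and 4.14 (3.06 to 5.73). Rora, a transcription factor of this lineage, was 2.53 (2.20 to 2.89) and 3.46 (3.12 to 3.83) higher, and Il1r1, the interleukin 1 receptor, 5.17 and 5.11 against 1 Sham UMI. Cd163l1, a scavenger receptor of gamma-delta T cells, was 4.39 (3.64 to 5.41) and 3.81 (3.02 to 4.86) higher. Il17a and Cd163l1 lead the gamma-delta cluster 15, which held 4, 45 and 85 cells of Sham, AAA_7 and AAA_14, so that these ratios and the cluster are 1 observation. Without the top cell of each library Il17a was 6.37 in AAA_14 and 5.24 in AAA_7. The list median was 2.35 with cells thinned (AAA_14) and 1.97 with 5 counts added (AAA_7), and 0.15 and 0.10 as a mean over cells.

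Regulatory T cell genes were also higher than in Sham in both libraries, and activation and checkpoint genes in AAA_7. Of 10 regulatory genes, 7 were at least 2-fold higher in AAA_14 and 8 in AAA_7, with medians of 1.22 (0.28 to 1.86, centred 0.78) and 1.52 (0.82 to 2.33, centred 1.11), and of 11 activation and checkpoint genes 6 and 8, with medians of 1.16 (−0.42 to 1.95, centred 0.72) and 1.27 (0.64 to 2.23, centred 0.86). Ctla4, an inhibitory receptor of regulatory T cells, was 1.21 (0.99 to 1.44) and 2.01 (1.78 to 2.25) higher, and Il2ra, the high-affinity interleukin 2 receptor chain, 1.86 and 2.33, with 23.4% of its AAA_7 UMIs in 1 cell. Areg, a growth factor made by tissue regulatory T cells, was 3.25 and 4.94 higher (1.90 and 3.96 with a limit of 20%), with 41.8% and 30.3% of its UMIs in 1 cell. Areg is also among the leading genes of the type 2 innate lymphoid cluster. Of the regulatory genes 3 of 10, and of the cytotoxic genes 3 of 9, are markers of another class. Type 1 genes had medians of 1.46 (−0.60 to 3.58, 5 of 8 higher) and 1.93 (−0.27 to 3.53, 6 of 8 higher), led by Cxcr6 (ENSMUSG00000048521, chromosome 9, 123806475 to 123811760), a homing receptor of tissue T cells, at 3.58 (3.16 to 4.08) and 3.53 (3.09 to 4.05). Cytotoxic genes had medians of 0.58 (0.18 to 2.05) and 1.26 (0.42 to 2.80), centred 0.14 and 0.85, and naive and recirculating genes −0.29 (−0.81 to 0.16) and −0.69 (−1.16 to 0.51), with the lymph node homing receptor Ccr7 at −1.11 in AAA_14. As means over cells the regulatory medians were 0.13 and 0.09 and the activation medians 0.09 and 0.08.

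Between AAA_14 and AAA_7, T cells differed less: the medians were 0.54 (−0.10 to 1.04) for type 17, −0.46 (−1.35 to 0.05) for type 1, −0.34 (−1.35 to 0.02) for regulatory, −0.60 (−1.21 to 0.55) for activation, −0.29 (−0.79 to −0.17) for cytotoxic and −0.04 (−0.34 to 0.51, and −1.11 with a limit of 5%) for naive genes. Blk (1.88), AY036118 (1.46) and Tmem176a (1.09) led the genes higher in AAA_14 and Klra7 (−2.82), Mir142hg (−2.46) and Hist1h2ap (−1.91) those lower. Cell cycle medians of T cells were 0.15, 0.24 and −0.14 for AAA_14 over Sham, AAA_7 over Sham and AAA_14 over AAA_7. The first was −0.29 when centred and −0.24 with TMM factors, the second −0.17 and −0.23, and the third 1.46 with a limit of 5%. Dissociation medians were 0.18 (0.02 to 0.43), 0.68 (0.13 to 1.26) and −0.33 (−1.01 to 0.05), the first of which was −0.26 when centred. The ranking of genes lower than in Sham held Hist1h1b (−2.76), Hist1h2ae (−2.42, with 28.1% of Sham UMIs in 1 cell) and Ccl3 (−2.92, with 24.7% of Sham UMIs in 1 cell) in AAA_14. Ccl3 turned to 3.37 with doublets kept and to 3.62 with a limit of 20%.

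Lars2, the gene of the mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666), was higher than in Sham in each compared class of both libraries. In T cells Lars2 stood at 11.3 CPM in Sham, 439 in AAA_7 and 290 in AAA_14, ratios of 5.25 (4.74 to 5.88) and 4.66 (4.15 to 5.28). In B cells the Lars2 ratios were 5.11 (4.414 to 6.002) and 4.55 (3.87 to 5.44), in NK cells 6.61 (4.70 to 12.50) and 6.06 (4.15 to 11.96) against 1 Sham UMI, and in neutrophils it was 22.3-fold (9.70 to 92.7) and 16.6-fold (7.25 to 68.7) higher.

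Cell cycle genes were higher in AAA_14 B cells than in B cells of either other library. Against Sham, 15 of 16 members were at least 2-fold higher, with a median log2 ratio of 2.4997 (1.39 to 3.04, centred 2.18), and against AAA_7 also 15 of 16, with a median of 1.85 (1.26 to 2.33). Cdk1, the kinase that drives entry into mitosis (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938), had 758 UMIs against 6 in Sham (4.03, 3.01 to 5.59, and 1.77 with cells thinned), and Rrm2, which makes deoxynucleotides for DNA synthesis, 736 against 10 (3.29, 2.48 to 4.43). Cluster 13, led by genes that include Rgs13 and Mef2b and high in cell cycle genes, held 193 of 1259 AAA_14 B cells but 5 of 415 in Sham and 8 of 455 in AAA_7, and 99.6% of the Cdk1 UMIs of AAA_14. Rgs13, a signalling regulator of germinal centre B cells, was 3.59 (2.49 to 5.35) and Mef2b, a transcription factor of the same stage, 3.07 (2.249 to 4.202) higher in AAA_14 than AAA_7. As genes that lead cluster 13 they are not independent of it. With at least 500 genes per cell that cluster stayed unnamed and outside the class, and the medians were −0.02 and 0.01, with Cdk1 at −1.65 and Rgs13 at −1.44. The median over AAA_7 was 0.63 with a limit of 20%, and as means over cells the medians were 0.17 and 0.18. AAA_7 over Sham had a cell cycle median of 0.55 (0.07 to 1.22), which was −0.03 with at least 500 genes and 1.28 with a limit of 20%.

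Activation genes of B cells were lower in AAA_14 than in AAA_7 for 5 of 10 members at 2-fold (median −0.97, −1.37 to −0.20, and −0.01 as a mean over cells). Against Sham 4 of 10 were at least 2-fold lower, and the list had no clear direction (median −0.55, −1.27 to 0.26, centred −0.86). It was 0.05 with cells thinned, 0.02 as a mean over cells and −0.06 with a limit of 20%. Cd83, a surface marker of activated B cells, was −1.33 (−1.42 to −1.23) against Sham and −1.14 against AAA_7, Cd69, an early activation marker, −1.17 against Sham, and Nr4a1, a gene induced by antigen receptor signalling, −1.27 and −1.63. Nr4a1 and Egr1 are also on the dissociation list, which was lower in AAA_14 than in Sham as well. These genes therefore cannot tell activation from a response to digestion. Gpr183, a receptor that positions B cells in lymphoid tissue, was −2.47 (−2.60 to −2.33) and Wfdc17 −3.32 against Sham, Hspa1b, a heat shock chaperone, −1.86 against AAA_7 and −3.83 there with a limit of 5%. Basp1 (3.93, 3.27 to 4.78) and Pclaf, a replication factor (3.58, 3.16 to 4.06), were higher in AAA_14 than Sham. Igll1 was −5.08 in AAA_14 and −1.58 there with cells thinned, with 63.0% of its 73 Sham UMIs in 1 cell. In AAA_7 Igll1 had 0 UMIs, and with at least 500 genes its ratio over Sham turned to 0.40. The AAA_7 activation median over Sham was −0.17 (−0.75 to 1.15). Genes higher in AAA_7 than Sham included Mir142hg (2.93), Psap (2.33) and S100a6 (4.31, 43.3% in 1 cell), and genes lower were Hist1h1e (−3.79) and Rgs1 (−2.64). For AAA_14 over Sham, AAA_7 over Sham and AAA_14 over AAA_7, follicular genes had medians of −0.08, 0.28 and −0.23 (−0.62 to 0.00, −1.70 with a limit of 5% and 0.12 as a mean over cells), B1 and innate-like genes 0.23, 1.11 (−0.20 to 4.31) and −0.50, antigen presentation genes −0.01, 0.05 and −0.07, and dissociation genes −0.59 (−0.96 to −0.41), −0.14 and −0.36, the last of which was 0.15 as a mean over cells.

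Of 11 effector genes of NK cells 4 were at least 2-fold lower in AAA_14 than in Sham (median −0.56, −1.31 to 0.59) and 2 in AAA_7 (−0.57, −1.04 to 0.59), so the list as a whole had no clear direction. None differed 2-fold between AAA_14 and AAA_7 (median 0.05). Ccl5, a chemokine of cytotoxic cells, was −1.10 (−1.16 to −1.04) and −1.17 (−1.24 to −1.11), and Gzma, the gene of granzyme A, −1.03 (−1.11 to −0.95) and −0.75 (−0.83 to −0.67). S100a4, a calcium-binding protein of motile cells, was 2.81 (2.25 to 3.48) higher in AAA_14, and Mapk3 3.71 and 4.13 higher against 1 Sham UMI. Klra1 (−2.54) and Hist1h4i (−2.46) were lower in AAA_14, and Hist1h1e (−3.55) and Gpr18 (−2.56) in AAA_7. Between AAA_14 and AAA_7, Tmem176a (2.90), H2-Ob (2.46, and 1.21 with a limit of 20%) and Hist1h1e (2.0047) were higher and Hspa1b (−2.11), Nfkbid (−1.70) and Hspa1a (−1.60) lower. Dissociation medians were 0.10, 0.20 (0.04 to 0.89, −0.03 with TMM factors) and −0.43 (−0.93 to −0.08), and cell cycle medians 0.26 (−0.23 with cells thinned, −0.02 with TMM factors), 0.79 (0.17 to 1.66, and 0.19 with cells thinned) and −0.52, for AAA_14 over Sham, AAA_7 over Sham and AAA_14 over AAA_7.

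**Figure D2:**
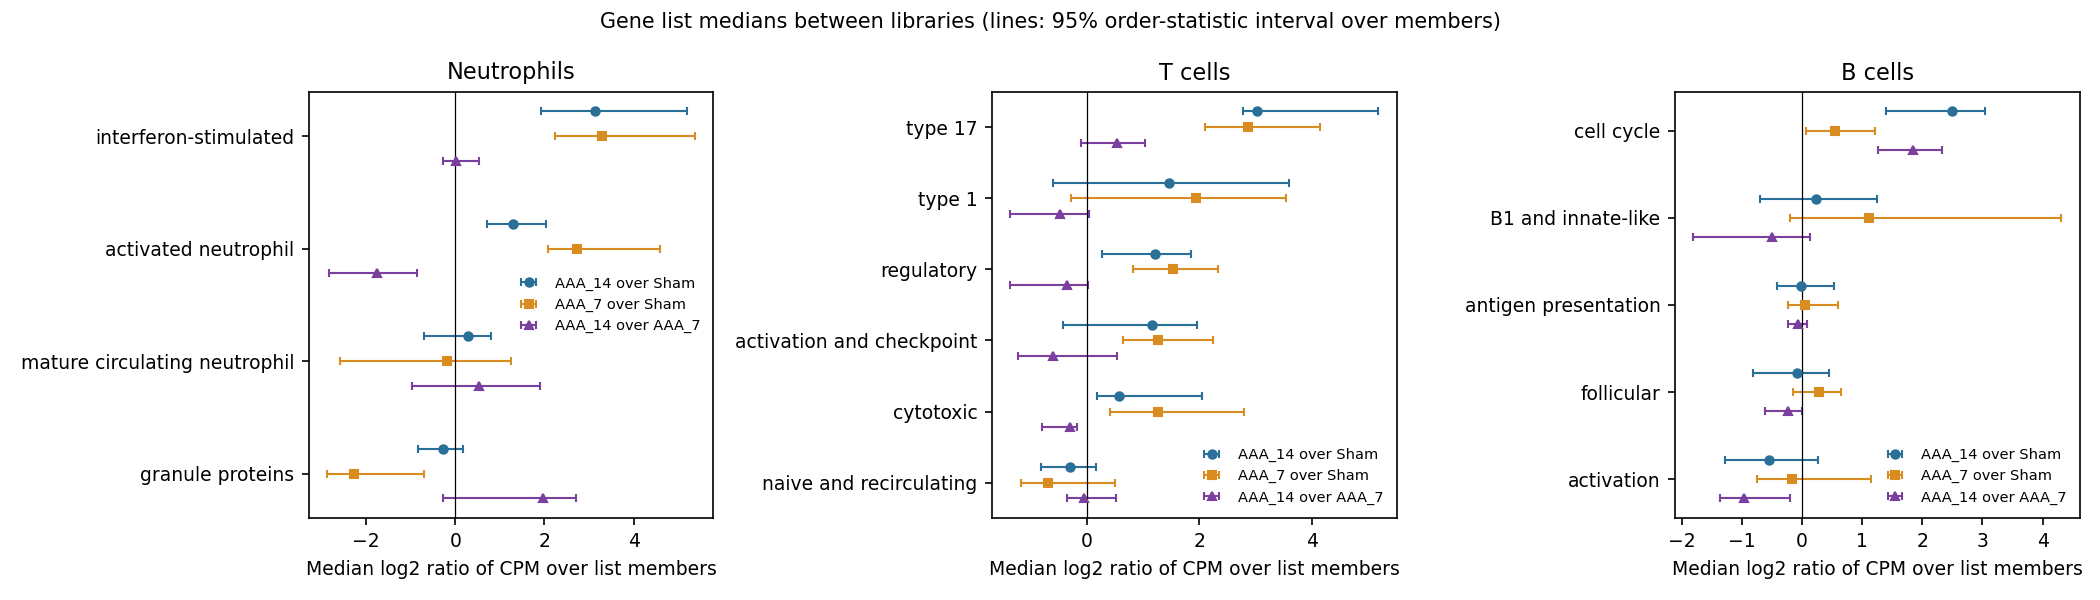
Points give the median log2 ratio of CPM over the members of gene lists (horizontal axis) in neutrophils, T cells and B cells for the 3 pairs of libraries, and lines the 95% interval over members. Interferon-stimulated genes of neutrophils (3.14 in AAA_14 over Sham) and type 17 genes of T cells (3.03) lie far above 0.

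Phagocytes could be compared only between AAA_14 and AAA_7. MHC class II genes, which present antigen to helper T cells, were higher in AAA_14, while the list medians of hypoxia, lipid-associated and protease genes were higher in AAA_7. Of the lipid-associated genes 11 of 14 lay within 2-fold, and of the proteases 9 of 18. Of 9 MHC class II genes 7 were at least 2-fold higher in AAA_14, with a median log2 ratio of 1.30 (0.89 to 1.35). Ciita, the master activator of these genes (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418), was 1.99 (1.75 to 2.24) higher, Cd74, the invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), 1.35 (1.33 to 1.36) with 16435 against 6463 CPM, H2-Ab1 1.34 (1.31 to 1.36) and H2-Aa 1.03 (1.00 to 1.05). Interferon-stimulated genes had a median of 0.60 (0.22 to 0.89), with Rsad2 at 0.88, Ifit3 at 1.04 and Isg15 at −0.98, MHC class I genes 0.55 (0.04 to 0.82), with their activator Nlrc5 at 1.17, and early monocyte genes 0.79 (−0.13 to 1.05), with Plac8 at 1.05 and Ly6c2 at 0.86.

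Among the phagocyte genes named here, the largest ratio was that of Retnla, a secreted product of alternatively activated macrophages (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461). Retnla had 8347 UMIs in AAA_14 and 89 in AAA_7, or 706 against 16.5 CPM, a log2 ratio of 5.41 (5.12 to 5.74), with 78.6% of the UMIs in 1 cluster. The value was 6.04 with cells thinned and 0.41 as a mean over cells. Ccl24, an eosinophil attractant, was 1.74 (1.45 to 2.05) higher. Both lead phagocyte cluster 17, so their ratios are not independent of that cluster. It held 3.82% of AAA_7 and 8.21% of AAA_14 phagocytes, a smaller difference than that of Retnla. Tissue-resident macrophage genes as a list had a median of 0.23 (−0.06 to 0.62), with 3 of 15 members at least 2-fold higher. Among other genes higher in AAA_14 were Fosb (1.38), Slco2b1 (1.54), Leng8 (1.83), Pnisr (1.43), AY036118 (1.75) and the monocyte attractant Ccl2 (1.27, 868 against 360 CPM), in a chemokine list whose median was 0.05 (−0.32 to 0.58).

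Of 10 hypoxia genes 6 were at least 2-fold lower in AAA_14 than in AAA_7 phagocytes, with a median of −1.12 (−2.74 to −0.62). Vegfa, the vascular growth factor (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369), was −2.96 (−3.14 to −2.78), and in the glycolysis list (median −0.50, −1.39 to −0.06) the glucose transporter Slc2a1 was −2.25 and the lactate exporter Slc16a3 −2.08. Lipid-associated macrophage genes had a median of −0.70 (−2.01 to −0.31, 3 of 14 lower). Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), was −4.31 (−4.57 to −4.07), −3.65 with cells thinned and −2.79 with a limit of 20%, and Spp1, the gene of osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), −2.94 (−3.02 to −2.87), with 24.5% of a library's UMIs in 1 cell. Of 18 matrix-degrading proteases 7 were lower and 2 higher (median −0.48, −1.63 to −0.15), and 2 of the 18 are markers of another class. Mmp12, macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), was −3.21 (−3.38 to −3.05), with 31.7% of a library's UMIs in 1 cell, and Ctsk, a collagen-degrading cathepsin, −2.21 (22.2% in 1 cell). As means over cells the hypoxia, lipid and protease medians were −0.13, −0.10 and −0.04. Spp1, Thbs1 (−2.42), Vegfa and Adora2b (−2.94) also lead cluster 6, so their ratios and that cluster are 1 observation.

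Of 15 inflammatory genes 7 were at least 2-fold lower in AAA_14 phagocytes (median −0.36, −1.73 to 0.23). Il1b, the gene of interleukin 1 beta, was −2.0024 (−2.04 to −1.96) with 664 against 2659 CPM, Ptgs2, which makes prostaglandins, −2.33 (−2.40 to −2.27), and Clec4e, a receptor for dead cells and mycobacteria, −2.07 (−2.15 to −1.98). Flrt3 (−4.34), Inhba, an activin subunit (−4.01, 22.5% in 1 cell, −2.65 with doublets kept), Cxcl3 (−2.60, 46.1% in 1 cell) and Mfge8 (−3.38, 52.0% in 1 cell) ranked among the lowest. Mfge8 was −2.38 without the top cells, −1.50 with cells thinned and 0.01 as a mean over cells. Smaller list medians were −0.22 (−1.31 to 0.75) for protease inhibitors, with Cstb at −1.31, −0.19 (−0.87 to 0.61) for wound repair, 0.28 (−0.05 to 0.55) for complement, −0.13 (−0.36 to 0.13) for oxidative phosphorylation, 0.06 (−0.70 to 0.35) for iron and heme handling, −0.19 (−0.34 to 0.03, and 0.91 with doublets kept) for cell cycle and 0.29 (−0.40 to 0.76) for dissociation genes, with Ier3 at −1.55.

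**Figure D3:**
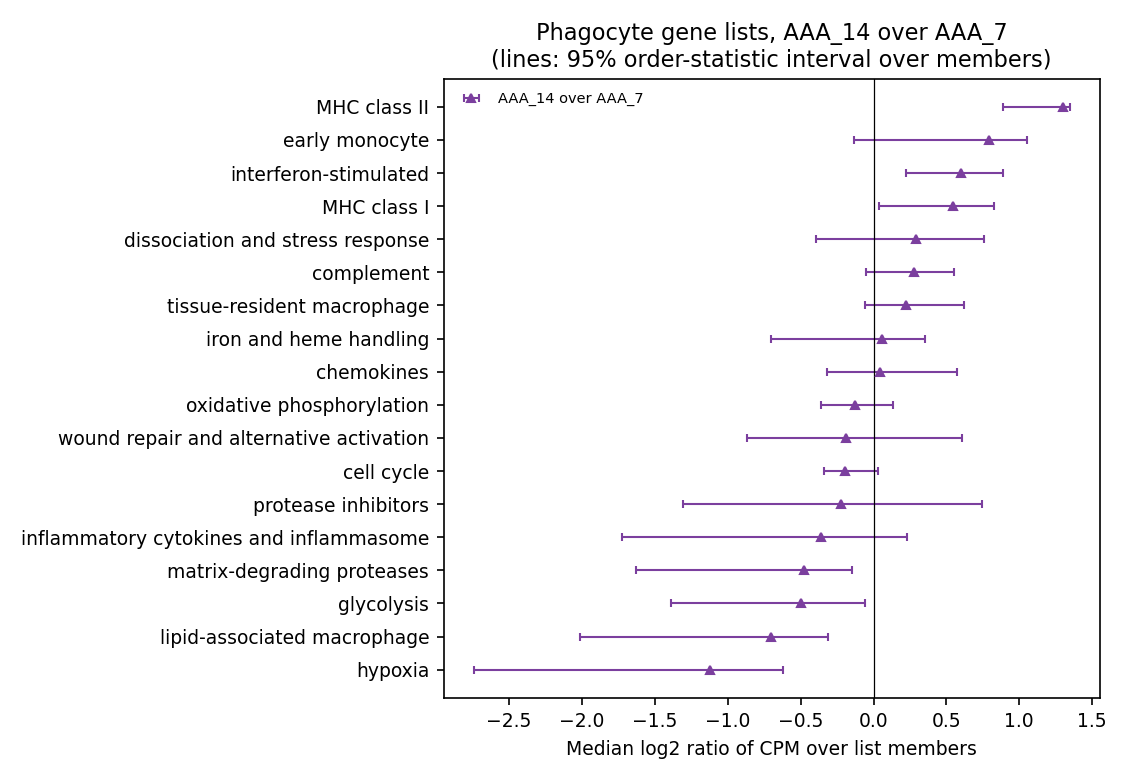
Points give the median log2 ratio of CPM over the members of each phagocyte gene list, AAA_14 over AAA_7 (horizontal axis), and lines the 95% interval over members. MHC class II genes have the highest median, 1.30, and hypoxia genes the lowest, −1.12.

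In dendritic cells, 6 of 16 cell cycle genes were at least 2-fold higher in AAA_14 than in AAA_7 (median 0.80, 0.35 to 1.30), with Birc5, an inhibitor of apoptosis in dividing cells, at 2.25 (1.37 to 3.47). These cells had a median of 12934 UMIs in AAA_14 and 6315 in AAA_7, and the list median was 0.19 with cells thinned, 0.49 with 5 counts added and 0.07 as a mean over cells. Antigen presentation genes had a median of 0.39 (0.10 to 0.58), with Ciita at 1.17 (0.95 to 1.39), and maturation genes 0.23 (−1.11 to 1.10, and −0.37 with cells thinned), with Ccr7 at −1.11, Cd80 at −1.19 and Tnfrsf4 at 1.64 (0.24 with cells thinned). Dissociation genes had a median of −0.67 (−1.40 to −0.27). The ranking of higher genes was led by genes of single cells: Mptx1, Spink4 and Agr2, known from intestinal epithelium, were at least 293-fold, 112-fold and 44.9-fold higher in AAA_14 with 99.97%, 99.86% and 99.83% of their UMIs in 1 cell, and were −0.51, 0.22 and −0.51 without it. Adipocyte and liver genes Cfd (−10.88), Cyp2e1 (−10.49) and Car3 (−9.24) were lower, with 68.2%, 67.0% and 48.5% of the AAA_7 UMIs in 1 cell. Without the top cells they were −9.55, −10.52 and −8.51. Their size depended on the filters. Cfd, Cyp2e1 and Car3 were −2.25, −2.12 and −1.21 with a limit of 20% and −2.60, −1.74 and −2.10 with a limit of 5%, and Cfd was −2.48 with doublets kept.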

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

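Both results below were chosen because cells outside the compared classes were above their Sham level in AAA_14, and no explanation was tested for either. Plasma cells (cluster 12, led by the immunoglobulin genes Igha, Ighg2c, Ighg1 and Jchain), which secrete antibody, were 3.694% (3.19 to 4.25%) of AAA_14 cells, 0.409% (0.133 to 0.951%) of Sham and 0.763% (0.489 to 1.13%) of AAA_7. With a mitochondrial limit of 5% they were 10.7% of AAA_14 and 1.50% of Sham, and with no limit 2.19% and 0.222%. The unnamed cluster 23, led by the matrix genes Col1a1, Col3a1, Cilp and Loxl1 and holding smooth muscle and fibroblast markers together, was 1.304% (1.01 to 1.66%) of AAA_14, 0.245% (0.0506 to 0.715%) of Sham and 0.318% (0.153 to 0.584%) of AAA_7. The CD45 bead selection acts against cells of the second kind, so this share depends on how complete the selection was in each library.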

How the results depend on the processing

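Shares without a mitochondrial limit or with a limit per library, the 20% limit for genes and lists, totals without mitochondrial genes and ratios without the top cells were chosen after the data were seen. No paired analysis was possible because each group was 1 library. Depth limits what could be seen: a count of 0 among 1223 Sham cells allows a share of 0.245%, and the median UMIs per cell were 3640 in Sham, 2533 in AAA_7 and 6740.5 in AAA_14. With a limit of 5%, 133 Sham cells remained and T, B and NK cells of Sham were too few to compare. Of the values computed under alternatives for lists that answer a comparison, 278 stayed within the interval, 25 moved and 1 reversed, and for the other lists 784 stayed, 48 moved and 8 reversed. For named genes 3123 stayed, 1449 moved and 22 reversed, and for shares that answer a comparison 78 stayed and 54 moved, with 140 and 58 for the other shares. Where no cause is given below, the cause was not tested.

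Shares moved with the mitochondrial limit and with other settings. The mitochondrial part of UMIs differed between classes, at 8.70% in Sham B cells and 2.08% in Sham neutrophils. At 5%, phagocytes were 0% of Sham, 27.9% of AAA_7 and 32.7% of AAA_14, neutrophils 72.2% of Sham and 25.6% of AAA_14, T cells 1.50% of Sham and 3.99% of AAA_14, and B cells 1.50% of Sham and 4.56% of AAA_14. At 20%, phagocytes were 0.537% of Sham, 33.5% of AAA_7 and 16.5% of AAA_14, neutrophils 3.96% of Sham and 12.5% of AAA_14, T cells 26.5% of Sham, 13.2% of AAA_7 and 14.8% of AAA_14, and B cells 53.3% of Sham and 40.6% of AAA_14. With a limit per library, phagocytes were 0.540% of Sham and 16.6% of AAA_14, neutrophils 3.92% of Sham, 23.8% of AAA_7 and 12.5% of AAA_14, T cells 29.9% of Sham and 16.4% of AAA_14, and B cells 53.0% of Sham and 40.3% of AAA_14. With no limit, phagocytes were 35.5% of AAA_7 and 17.4% of AAA_14, neutrophils 3.305% of Sham and 11.5% of AAA_14, T cells 29.88% of Sham, 12.85% of AAA_7 and 13.7% of AAA_14, and B cells 52.9% of Sham and 40.5% of AAA_14. With doublets kept, phagocytes were 1.94% of Sham and 23.1% of AAA_14, and T cells 30.45% of Sham, 13.2% of AAA_7 and 15.6% of AAA_14. With each library clustered on its own, phagocytes were 0% of Sham (which allows 0.245%), and T cells 42.4% of Sham and 11.5% of AAA_7. With cells named one by one, phagocytes were 23.3% of AAA_14, T cells 16.3% of AAA_7 and B cells 39.1% of Sham. With cells thinned, T cells were 40.3% of Sham, and B cells 37.0% of Sham and 16.1% of AAA_7. At a Leiden resolution of 0.5, T cells were 16.4% of AAA_7 and 16.5% of AAA_14. With at least 500 genes per cell, B cells were 21.0% of AAA_14, since cluster 13 then stayed unnamed.

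The mean over cells of log2 levels is another scale, on which genes with 0 UMIs in most cells move little by construction. On it the phagocyte medians of AAA_14 over AAA_7 were −0.041 for proteases, −0.10 for lipid-associated and −0.13 for hypoxia genes, with Mfge8 reversed at 0.0059. B cell medians were 0.17 (cell cycle, AAA_14 over Sham), and over AAA_7 0.18 (cell cycle), −0.013 (activation) and 0.12 (follicular, reversed). Neutrophil medians were 0.54 (activated) and 0.95 (interferon) for AAA_14 over Sham and 0.61 (interferon) for AAA_7 over Sham. T cell medians of AAA_14 over Sham were 0.13 (regulatory) and 0.15 (type 17), with Ccl3 reversed at 0.029, and those of AAA_7 over Sham 0.079 (activation), 0.094 (regulatory) and 0.10 (type 17).

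With at least 500 genes per cell, cluster 13 left the B cells, and the AAA_14 over Sham cell cycle median was −0.0246, with H2afz at −0.0246, Cdk1 at −1.65 and Rrm2 at −0.55. The AAA_7 over Sham median was −0.0251, with Igll1 at 0.40 and Top2a at −0.41, and that of AAA_14 over AAA_7 0.010, with Rgs13 at −1.44. The type 17 median of AAA_14 over Sham was 2.57 there, 2.45 with 5 counts added (AAA_7 over Sham 1.97), 2.58 when centred, 2.64 with TMM factors, 2.35 with cells thinned and 2.49 at 20%. Dissociation medians reversed in AAA_14 over Sham neutrophils at 5% (−0.23), in AAA_14 over Sham T cells when centred (−0.26) or with TMM factors (−0.21), and in AAA_7 over Sham NK cells with TMM factors (−0.027). The NK cell cycle median of AAA_14 over Sham reversed with TMM factors (−0.016) and with cells thinned (−0.23). At 5% the activated neutrophil median of AAA_14 over Sham was 0.35 and Ahnak in B cells of AAA_14 over AAA_7 0.22. At 20% the B cell cycle median of AAA_14 over AAA_7 was 0.63. Without mitochondrial genes in the total the phagocyte MHC class II median was 1.36. In T cells of AAA_14 over Sham, Ccl3 was 3.37 with doublets kept and 3.62 at 20%, and Ier3 0.72 and 0.95. In dendritic cells of AAA_14 over AAA_7, Mptx1 was −1.74, Spink4 −0.15 and Agr2 −0.15 at 5%, and Mptx1 and Agr2 were both −0.52 with at least 500 genes, −0.54 at 20% and −0.51 without the top cells, since 1 cell holds nearly all of their UMIs.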

Other observations

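The tests of few Sham phagocytes, of the library-wide shift of Lars2, of an interferon shift of the whole library and of treatment were chosen after the results were seen. The other tests were fixed before they were run, but the patterns and clusters they address were found in these same data. Levels of secreted ligands and their receptors across classes were described for fixed pairs, as levels and not as signalling. Cxcl2, a neutrophil attractant, was highest in neutrophils of all 3 libraries, at 6625 CPM in Sham, 37972 in AAA_7 and 12817 in AAA_14, and its receptor Cxcr2 was highest in neutrophils as well (395, 563 and 693 CPM). Csf1, a growth factor for macrophages, was highest in AAA_7 neutrophils (1006 CPM), and its receptor Csf1r in phagocytes (524 CPM in AAA_7 and 824 in AAA_14). The monocyte attractants Ccl2 and Ccl7 were highest in AAA_14 phagocytes (868 and 1092 CPM), and in AAA_7 in type 2 innate lymphoid cells, on only 17 and 35 UMIs.

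Apoe, a lipid carrier, was highest in phagocytes (11348 CPM in AAA_7 and 14602 in AAA_14), as were Gas6, which bridges dying cells to phagocytes (242 and 267 CPM), and its receptor Axl (139 and 196). Ifng was highest in NK cells of each library (451, 347 and 358 CPM in Sham, AAA_7 and AAA_14), and Ccl22, a T cell attractant, in dendritic cells (179, 86.1 and 108 CPM). Osm, a cytokine of the interleukin 6 family, was highest in neutrophils of Sham (936 CPM) and AAA_14 (1052 CPM), but in AAA_7 in phagocytes (248 CPM).

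Phagocytes were few in the Sham library. Without any mitochondrial limit they were 0.6665% (0.427 to 0.990%) of Sham cells, so the limit does not account for it. They were 8.333% (4.51 to 13.8%) of Sham phagocytes, neutrophils and dendritic cells together, against 52.6% (50.3 to 54.9%) in AAA_7 and 47.9% (45.9 to 50.0%) in AAA_14, so dilution by lymphocytes alone does not either. Recovery of cells may differ between libraries, which stays open together with the treatment because there was 1 Sham library.

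Lars2 and mitochondrial genes differed between libraries in every compared class. The smallest Lars2 fold over Sham within a class was 16.59 (lower bound 7.25), and the mitochondrial share was at least 3.40-fold lower in AAA_7 than in AAA_14 in each class. This argues against the mix of classes as the cause. Different clusters made up the classes, and composition within a class was not tested. The patterns of Lars2 and of the mitochondrial share were not alike. Lars2 was lowest in Sham, while the mitochondrial share was lowest in AAA_7, at 1.84% of T cell UMIs against 8.05% in Sham and 7.07% in AAA_14. Preparation of the libraries may account for either pattern and stays open, since the largest number of libraries in a group was 1.

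Interferon-stimulated genes were higher in AAA_14 than in Sham neutrophils. With cells thinned to 1000 UMIs the median was 3.045 (1.28 to 5.04). CPM already divide by the total, and thinning keeps each gene's expected part of a cell's UMIs. The thinned median therefore does not decide on sequencing depth. The median ratio of neutrophil CPM to the highest other class was 1.447 (0.651 to 1.88), which argues against free RNA. A shift of the whole library stays open. The list median was 2.184 (1.01 to 3.15) in B cells and 2.15 (1.00 to 3.59) in T cells, inside the neutrophil interval of 1.92 to 5.19. In NK cells it was 1.08, below that interval, but its own interval of 0.54 to 4.80 overlaps it. An effect of the treatment may also account for the difference from Sham, and cannot be told apart from the library with 1 library in a group.

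Without cluster 13 the B cell cycle median of AAA_14 over Sham was −0.07966 (−0.466 to 0.709). That cluster holds 89.2% of the list's UMIs in AAA_14 B cells, so leaving it out fixes this outcome and tests no explanation. Without the gamma-delta cluster 15, which held 52.3% of the list's UMIs in AAA_14 T cells, the type 17 median of AAA_14 over Sham was 3.86 (2.68 to 5.79). The cells of that cluster were therefore not the whole of that difference. Gamma-delta T cells in other clusters, if any, were not left out. With cells thinned, the activated neutrophil median of AAA_14 over AAA_7 was −1.336 (−2.45 to −0.683). Because CPM already divide by the total, this does not decide on sequencing depth either.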
